A study of Homo sapiens with 12 samples.

How the data were processed

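The series profiled mRNA from Beas-2b cells, an immortalised line of human bronchial epithelial cells, by sequencing of poly(A)-selected RNA. Wild type cells and cells in which ANT1 had been knocked out by CRISPR were each kept in control medium or treated with bleomycin, which breaks DNA and was used, per the labels, at 10 mg/ml for 2 days to induce senescence. ANT1, the adenine nucleotide translocase 1, is encoded by SLC25A4 and exchanges ADP and ATP across the inner mitochondrial membrane. Each of the 4 groups had 3 libraries, which the series' design text calls biological replicates. How many knockout clones they came from is not given in the sources used here, so genotype and clone cannot be separated.

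The authors deposited a table of raw counts and a table of FPKM values for the same 12 libraries and 58735 annotated genes. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build is not given in the sources used here. All 58735 gene identifiers occur in GENCODE release 29, and 58690 of them have the same chromosome, start, end and strand there, on GRCh38. Whether the counting used strand is not given either, so reads of overlapping and antisense genes may be mixed. Reads of near-identical copies may also be split between genes. The values of ribosomal protein and histone genes, the SAA, CYP4F and CXCL families and the translocase paralogs SLC25A5 and SLC25A6 are uncertain to that extent. The deposited FPKM of a gene equalled its count (within 0.1%) divided by its length and by a factor per library, which lay between 0.963 and 1.05 times the library's total. Gene names in the 2 tables differed for 27 genes, so genes were joined by identifier. Where 1 symbol belongs to 2 identifiers, the identifier is written after it. Every row named a gene, so 0 were left out for that reason.

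The deposited counts summed to between 15.75 and 21.92 megacounts per library. A count of 0 in a library allows an abundance of up to 3 counts, between 0.137 and 0.190 CPM (counts per megacount of the library) over the 12 libraries. Intervals and floors of that kind cover counting error only.

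Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3). Low counts were removed with filterByExpr, which left 16702 genes. Libraries were scaled with TMM factors, dispersions were estimated with estimateDisp, and glmQLFit was run with robust estimation. A single fit held all 12 libraries and 4 group means, so that the groups shared an estimate of the spread. A total of 5 contrasts were tested: bleomycin against control in wild type and in knockout cells, knockout against wild type in control medium and in bleomycin, and the interaction, which is the bleomycin response of knockout cells minus that of wild type cells on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. CPM values are given as mean ± SD with n = 3, from the TMM-scaled library sizes.

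A set of 34 gene lists was fixed before the data were examined. They were tested with limma's camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A list needed at least 5 tested members, which left the lists of leukocyte markers (2 of 10 members tested) and endothelial markers (3 of 8) untested. Each list was tested again with the correlation estimated from the data and with fry. The counts of members given as adjusted over the list alone come from the edgeR p-values of the members only. Exact permutation tests of library measures were two-sided, and with 3 libraries against 3 their smallest possible p is 0.1.

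Genes were named by a rule fixed before the data were examined. It took the 3 translocase genes SLC25A4, SLC25A5 and SLC25A6 in every comparison. It took the 5 rising and 5 falling protein-coding genes (6 and 6 for the interaction) with the largest change among those past the threshold with a mean log2 CPM of at least 1. For contrasts between 2 groups, every library of one group had to lie above every library of the other. For each list described, up to 4 members past the threshold with the smallest adjusted p were taken, or the members of highest CPM where fewer than 2 passed. Genes named outside the rule were chosen after their values were seen, which is not repeated at each of them. They include remaining called genes, such as GREM1, SPRTN and TNFAIP3, and list members that went against their list or did not pass. A few genes that the rule takes are not reported here.

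Genomic position was examined in windows of 10 Mb with at least 15 tested genes. The median log2 fold change of knockout against wild type was compared with 10000 random gene sets of the same size. A window was called when it passed in both media, with the same sign and a median of at least 0.2. The p-value of a window was changed from a doubled one-sided value to the share of random medians at least as far from their centre. This change came after a simulated window had been missed and after the count for the real libraries had been seen, and 0 windows were called with either. The change of the 10 nearest protein-coding genes outside the list was also divided by that of the members of the interferon-stimulated and NF-kB lists, with a 95% interval from resampling the members by window. Agreement of the bleomycin responses of the genotypes was measured over genes past the threshold in either of them, with Pearson's r and the orthogonal slope of knockout on wild type.

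Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (10 counts and 1 CPM in every library of a group), fits to only the groups compared, a block for the replicate number, limma on log2(FPKM + 1) and log2(FPKM + 0.1), lists without shared genes, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out replicate 2 of the knockout control group from every comparison, an offset per gene and library from a spline of GC content and transcript length, and limma-voom with sample quality weights.

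Calls of genes, lists and windows and the slope were tested on simulated counts for 16702 genes. The counts were drawn from the means, library sizes and dispersions of the real libraries, and no simulated library was made to stand apart. Far fewer genes were changed than bleomycin moved in the real libraries, so the recovery need not hold for the real contrasts. Calls of genes were tested with 200 genes changed, and the slope with 2000. In the simulated comparison of knockout with wild type in control medium, edgeR recovered 17 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 9 false calls. For knockout against wild type in bleomycin it recovered 17 of 67, 43 of 67 and 60 of 66, with 2 false calls. For bleomycin in wild type cells the numbers were 13 of 67, 40 of 67 and 56 of 66, with 7 false calls, and for bleomycin in knockout cells 21 of 67, 44 of 67 and 58 of 66, with 14 false calls. For the interaction it recovered 2 of 67, 27 of 67 and 50 of 66, with 4 false calls. In the order given, the false calls of edgeR were among 133, 122, 116, 137 and 83 calls. DESeq2 made 24 false calls in each of the simulated bleomycin comparison in wild type cells (158 calls) and the simulated interaction (121 calls). A list moved by 0.5 on the log2 scale was called in all 5 simulated comparisons, and 0 other lists without shared genes were. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often correlated genes give false list calls. A window of 49 genes moved 1.5-fold was called, with 0 others, and a slope of 0.8 was estimated as 0.805.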

Results

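Transcript levels were measured by RNA sequencing in 12 libraries of Beas-2b human bronchial epithelial cells. The libraries formed 4 groups of 3 biological replicates: wild type cells and ANT1 knockout cells, each in control medium or after bleomycin. The series title places the work in the study of pulmonary fibrosis and asks what role ANT1 has in it. Total counts, in megacounts, were 20.41, 21.92 and 18.47 in the wild type control libraries, 18.93, 16.91 and 18.7 in wild type bleomycin, 16.77, 16.59 and 18.31 in knockout control, and 15.75, 18.83 and 18.28 in knockout bleomycin. Total counts were compared between group means by exact permutation, where 3 libraries against 3 allow no p below 0.1. That smallest value was reached for knockout against wild type in control medium (17.2 against 20.3). There every knockout library had a lower total than every wild type library. The exact permutation p of the other comparisons ran from 0.3 to 0.9.

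The targeted gene was examined first. SLC25A4 (ENSG00000151729, chromosome 4, 185143241 to 185150382) was at 19.2 ± 3.22 CPM in wild type control, 22 ± 5.71 in wild type bleomycin, 5.62 ± 1.18 in knockout control and 4.60 ± 0.462 in knockout bleomycin (SD, n = 3). Every knockout library lay below every wild type library, with a highest knockout value of 6.97 CPM and a lowest wild type value of 16.1 CPM. The transcript was 3.42-fold lower in knockout cells in control medium (log2 fold change -1.78, SE 0.21, adjusted p = 0.0111, edgeR) and 4.78-fold lower in bleomycin (-2.26, SE 0.22, adjusted p = 0.000904). The call in control medium was lost without wild type control replicate 1 (adjusted p = 0.0515) or replicate 3 (adjusted p = 0.0622), within a range of 0.000335 to 0.0622 over the libraries left out in turn. Bleomycin left SLC25A4 without a called difference in wild type cells (0.19, SE 0.19, adjusted p = 0.452) and in knockout cells (-0.29, SE 0.23, adjusted p = 0.328). The paralogs SLC25A5 and SLC25A6, which encode the other widely expressed translocases, did not pass between genotypes in control medium (-0.09, SE 0.10, and -0.14, SE 0.10) or in bleomycin (0.03, SE 0.10, and 0.01, SE 0.10).

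**Figure D1:**
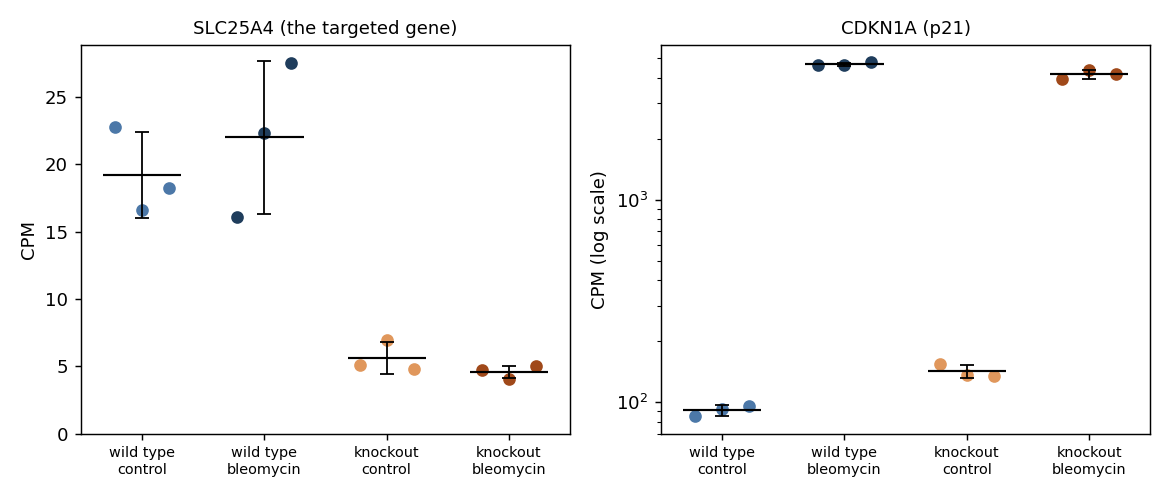
CPM of SLC25A4 (left, linear axis) and CDKN1A (right, log axis) in each library of the 4 groups. Points are libraries, the line is the group mean and the bar its SD (n = 3). The 6 knockout libraries lie at or below 6.97 CPM of SLC25A4 and the 6 wild type libraries at or above 16.1 CPM.

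Of the 12 libraries, replicate 2 of the knockout control group stood apart. Counts on the mitochondrial chromosome made up 0.364% of its total, against 3.86% to 5.13% in the other 11 libraries. Its counts differed from those of the other knockout control libraries by a chi-square per gene of 127 and 117, where replicates of the same group otherwise gave at most 18.6. It lay at -74.6 on the second principal component of log2 CPM, which held 9.68% of the variance, while the other 11 lay between -4.87 and 19.1. Its SLC25A4 level, 6.97 CPM, was the highest of the knockout libraries, 1.41 times the mean of the other knockout controls and 0.433 of the lowest wild type library. It was kept in the fit, and the values without it stand beside the gene groups that move with it.

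**Figure D2:**
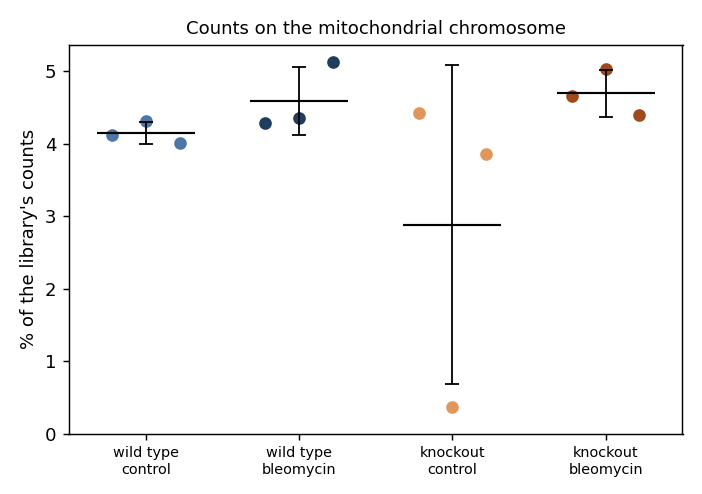
Share of each library's counts on the mitochondrial chromosome, in %, by group. Points are libraries, the line is the mean and the bar the SD (n = 3). Replicate 2 of the knockout control group lies at 0.364% and the other 11 libraries between 3.86% and 5.13%.

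Bleomycin against control in wild type cells asks how bronchial epithelial cells respond to a senescence-inducing DNA-damaging drug. Targets of p53 rose and mitosis genes fell. CDKN1A, which encodes the cell cycle inhibitor p21, rose 51.2-fold from 91.2 ± 5.35 to 4669 ± 81.2 CPM (SD, n = 3, log2 fold change 5.68, SE 0.11). MDM2, the ubiquitin ligase that degrades p53, rose 29.7-fold (4.89, SE 0.10), and the stress cytokine GDF15 rose 131-fold (7.03, SE 0.18). PLK1, a mitotic kinase, fell 7.64-fold (-2.93, SE 0.09), and CCNB1, cyclin B1, fell 5.99-fold (-2.58, SE 0.12). Among 16702 genes, 7262 passed edgeR's test, or 43.5%, with 3990 higher and 3272 lower, and 3060 of them changed at least 2-fold (2178 higher, 882 lower).

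Of the 28 p53 target genes, 27 rose, with a list median of 3.17 (camera adjusted p = 1.26e-25, and adjusted p = 0.00585 with an estimated correlation). Adjusted over the list alone, 27 rose and PLK2 (-0.32) fell, which over all genes passed without knockout control replicate 2 (adjusted p = 0.000437). All 28 mitosis genes fell, with a median of -1.67 (adjusted p = 4.79e-22, and adjusted p = 0.0446 with an estimated correlation), and 28 fell adjusted over the list alone. AURKA, a spindle kinase, fell 4.24-fold and HMGB2, a chromatin protein lost in senescent cells, fell 3.67-fold. Of the integrated stress response genes, 16 of 21 rose and 2 fell, the amino acid transporter SLC7A5 and VLDLR (median 1.61, adjusted p = 3.23e-06, and adjusted p = 0.00912 with an estimated correlation). The same numbers passed adjusted over the list alone. SESN2, a stress-induced inhibitor of mTORC1 signalling, rose 6.40-fold and the transcription factor ATF3 rose 9.13-fold.

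Of 34 genes of the senescence-associated secretory list, 24 rose and 5 fell (25 and 6 adjusted over the list alone), with a median of 1.98 and an adjusted p = 2.05e-09 (adjusted p = 0.0625 with an estimated correlation). The growth factor AREG rose 74.3-fold and the cytokine CSF2 17.4-fold. The members that fell were CCL2, CXCL6, IGFBP5, IGFBP6 and TNFRSF11B. GDF15 belongs to this list, the p53 list and the stress response list. Of 15 TGF-beta target genes, 9 rose and 2 fell, CYR61 and TGFB2 (9 and 3 adjusted over the list alone, median 0.54, adjusted p = 0.00642, and adjusted p = 0.108 with an estimated correlation). ACTA2, smooth muscle actin, rose 46.6-fold from 1.31 ± 0.405 to 62.0 ± 2.46 CPM, and LTBP2, an extracellular matrix glycoprotein, rose 4.80-fold.

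Glycolysis genes fell, 18 of 20, while PFKFB4 rose (18 and 1 adjusted over the list alone, median -0.85, adjusted p = 3.04e-08, and adjusted p = 0.121 with an estimated correlation). Lactate dehydrogenase A (LDHA) fell 3.21-fold and hexokinase 2 (HK2) 2.88-fold. Hypoxia response genes fell, 12 of 16, while ANGPTL4 and P4HA2 rose (12 and 2 adjusted over the list alone, median -1.02, adjusted p = 1.38e-05, and adjusted p = 0.108 with an estimated correlation). CA9, a carbonic anhydrase induced by hypoxia, fell 39.9-fold from 125 ± 26.9 to 3.13 ± 0.159 CPM. Cholesterol synthesis genes fell, 9 of 19, and 3 rose, IDI1, SC5D and SQLE (9 and 3 adjusted over the list alone, median -0.36, adjusted p = 0.0068, and adjusted p = 0.0625 with an estimated correlation). DNA replication genes fell, 12 of 28, and PCNA and TYMS rose (14 and 2 adjusted over the list alone, median -0.26, adjusted p = 0.00467, and adjusted p = 0.167 with an estimated correlation). The replicative helicase subunit MCM6 fell 2.18-fold. PCNA, the replication clamp and a p53 target, rose 1.91-fold.

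Of 15 BCL2 family genes, 8 rose and 2 fell, BID and BMF (9 and 2 adjusted over the list alone, median 1.07, adjusted p = 0.016, and adjusted p = 0.0915 with an estimated correlation). The pro-apoptotic BBC3 (PUMA) rose 13.3-fold, BMF fell 7.66-fold and the anti-apoptotic BCL2L1 rose 2.39-fold. Immediate early genes rose, 9 of 12, while MYC fell (9 and 1 adjusted over the list alone, median 0.78, adjusted p = 0.0183, and adjusted p = 0.171 with an estimated correlation). EGR2 had 79 counts in the wild type bleomycin group against 3 in the control group, a ratio of 28.5 with a 95% exact counting interval of 9.41 to 141. In edgeR EGR2 rose 16.6-fold without wild type control replicate 2 and 46.0-fold without replicate 3. Of 14 airway cell markers listed, 5 could be tested, and 3 rose (3 adjusted over the list alone), with a median of 2.92, also with FOXJ1 at its bound (adjusted p = 0.0467, and adjusted p = 0.167 with an estimated correlation). FOXJ1, PIFO and MUC5AC had 0, 7 and 2 counts over the wild type control libraries and 47, 51 and 217 in wild type bleomycin. These markers passed the filter on low counts only through bleomycin libraries, so the filter largely set the direction of the list. CAPS went from 289 to 298 counts and DNAI1 from 25 to 35. The airway list lost its call without wild type control replicate 1 (adjusted p = 0.087), wild type bleomycin replicate 3 (0.0526) or knockout control replicate 2 (0.105). The goblet cell mucin MUC5AC went from 2 to 217 counts over 3 libraries, a ratio of 118 (95% interval 32.2 to 977). FOXJ1, the master regulator of cilia formation, went from 0 to 47 counts, at least 17.0-fold higher against a floor of 3 counts over the group.

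Among protein-coding genes with a mean log2 CPM of at least 1 and no overlap between the groups, ABCA13, a lipid transporter, had the largest called increase. It went from 2 to 1827 counts over 3 libraries, a ratio of 990 (95% interval 274 to 8180). The next were CYP4F3, a fatty acid hydroxylase, 264-fold (8.05, SE 0.33; 455-fold without wild type control replicate 1), DSG3, the desmosomal cadherin of stratified epithelium, 250-fold (7.96, SE 0.36), FAM84A, 182-fold (7.51, SE 0.16), and PADI4, which converts arginine to citrulline, 137-fold (7.10, SE 0.35). Beside CA9, the largest decreases among such genes were in the epithelial transcription factor ELF3, 32.9-fold, the acute-phase gene SAA2, 17.5-fold, the helicase PIF1, 14.9-fold, and the mucin MUC1, 11-fold. All 10 passed with adjusted p-values from 4.95e-12 to 1.85e-05. With limma on log2(FPKM + 1), a scale that compresses low genes, 1173 genes changed at least 2-fold in place of 3060. Mitochondrially encoded genes (median -0.11, adjusted p = 0.821) and nuclear oxidative phosphorylation genes (median 0.01, adjusted p = 0.647) did not pass as lists.

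Bleomycin against control in knockout cells asks the same question in cells with low SLC25A4. The p53 targets rose and mitosis genes fell here too. CDKN1A rose 29.2-fold, from 142 ± 10.8 to 4152 ± 194 CPM (SD, n = 3, log2 fold change 4.87, SE 0.11), MDM2 rose 19.3-fold (4.27, SE 0.10), GDF15 55.2-fold (5.79, SE 0.17) and BTG2, an antiproliferative p53 target, 13.7-fold (3.78, SE 0.11). PLK1 fell 5.46-fold (-2.45, SE 0.09), CCNB1 5.61-fold (-2.49, SE 0.12) and TOP2A, topoisomerase II alpha, 3.10-fold (-1.63, SE 0.09). With edgeR, 7219 of 16702 genes passed, 3766 higher and 3453 lower, and 2862 of them changed at least 2-fold (2005 higher, 857 lower).

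Of 28 p53 target genes 27 rose, and PLK2 (-0.11) did not pass, although without knockout control replicate 2 it fell (-0.29, adjusted p = 0.0031) (27 adjusted over the list alone, median 2.67, adjusted p = 1.49e-26, and adjusted p = 0.0049 with an estimated correlation). Of 28 mitosis genes 27 fell, and NUSAP1 (-0.69) did not pass (28 adjusted over the list alone, median -1.58, adjusted p = 9.79e-22, and adjusted p = 0.0379 with an estimated correlation). Of the integrated stress response genes 15 of 21 rose, with DDIT3, the transcription factor CHOP, 9.46-fold higher, and SLC7A5 and VLDLR fell (15 and 2 adjusted over the list alone, median 1.2, adjusted p = 2.94e-06, and adjusted p = 0.00872 with an estimated correlation). Of the secretory genes 25 of 34 rose and 5 fell, the 5 named for wild type cells (25 and 5 adjusted over the list alone, median 1.97, adjusted p = 1.85e-09, and adjusted p = 0.0431 with an estimated correlation). AREG rose 33.3-fold and the chemokine CXCL2 7.17-fold. Cholesterol synthesis genes fell, 12 of 19, and SC5D rose (12 and 2 adjusted over the list alone, median -0.45, adjusted p = 0.00168, and adjusted p = 0.0379 with an estimated correlation).

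The other lists that passed in knockout cells lost their call with an estimated correlation. Glycolysis genes fell, 16 of 20, with LDHA 2.57-fold lower, and PFKFB4 rose (16 and 1 adjusted over the list alone, median -0.68, adjusted p = 2.94e-06, and adjusted p = 0.16 with an estimated correlation). Hypoxia response genes fell, 12 of 16, with BNIP3, a mitophagy receptor, 2.42-fold lower, and ANGPTL4 and P4HA2 rose (12 and 2 adjusted over the list alone, median -0.89, adjusted p = 0.00032, and adjusted p = 0.147 with an estimated correlation). TGF-beta targets rose, 8 of 15, with ACTA2 25.5-fold higher, and CTGF fell (8 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.00454, and adjusted p = 0.105 with an estimated correlation). DNA replication genes fell, 12 of 28, and PCNA and TYMS rose (12 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.00454, and adjusted p = 0.16 with an estimated correlation). Recombination repair genes fell, 7 of 16, with FANCD2, a Fanconi anaemia protein, 1.70-fold lower, and BRCA2 and PALB2 rose (7 and 2 adjusted over the list alone, median -0.25, adjusted p = 0.0402, and adjusted p = 0.302 with an estimated correlation). The recombination repair list lost its call without knockout control replicate 1 (adjusted p = 0.0803) or 3 (0.085) or knockout bleomycin replicate 1 (0.0572). Lysosome genes rose, 10 of 19, with the membrane protein LAMP1 1.98-fold and the sialidase NEU1 1.69-fold higher, and 1 fell (10 and 2 adjusted over the list alone, median 0.45, adjusted p = 0.0151, and adjusted p = 0.0982 with an estimated correlation). In wild type cells 8 lysosome genes rose and 2 fell (median 0.24, camera adjusted p = 0.135). There 5 recombination repair genes fell and 2 rose (median -0.20, camera adjusted p = 0.135). The BCL2 family list, which passed in wild type cells, did not pass in knockout cells (8 higher, 2 lower, median 0.52, camera adjusted p = 0.0505).

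Immediate early genes rose in knockout cells, 9 of 12, with ATF3 7.91-fold higher, while MYC fell (10 and 2 adjusted over the list alone, median 0.95, adjusted p = 0.00713, and adjusted p = 0.147 with an estimated correlation). Of 5 airway markers tested 3 rose (3 adjusted over the list alone, median 2.56, also with FOXJ1 at its bound, adjusted p = 0.0151, and adjusted p = 0.147 with an estimated correlation). FOXJ1, PIFO and MUC5AC had 0, 7 and 1 counts in knockout control, so here too the filter on low counts largely set the direction of the list. MUC5AC went from 1 to 210 counts, a ratio of 202 (95% interval 35.8 to 8013; in edgeR 150-fold, and 580-fold without knockout control replicate 3), and FOXJ1 from 0 to 41 counts, at least 13.1-fold higher. Interferon-stimulated genes fell, 11 of 26 (11 adjusted over the list alone), with a median of -0.59 and an adjusted p = 0.00454 (adjusted p = 0.617 with an estimated correlation). IFIT1 fell 2.52-fold (4.00-fold without knockout bleomycin replicate 2) and IFI44 1.63-fold, and the list of interferon-stimulated genes lost its call without knockout bleomycin replicate 1 (adjusted p = 0.0572). Ribosomal protein genes rose, 19 of 76, and RPL22 fell (2 higher adjusted over the list alone, median 0.35, adjusted p = 0.00351, and adjusted p = 0.617 with an estimated correlation). The mitochondrially encoded genes had a median of 0.57 (adjusted p = 0.0607; 0.00491 without knockout control replicate 1 and 0.00766 without replicate 3). Without knockout control replicate 2 the median of the mitochondrially encoded genes was 0.08 (adjusted p = 0.53), and the cytosolic ribosomal protein genes kept their call. In wild type cells 6 interferon-stimulated genes fell and 2 rose with bleomycin (median -0.33, camera adjusted p = 0.221). There 2 ribosomal protein genes rose and 0 fell (median 0.08, camera adjusted p = 0.725).

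Among protein-coding genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest called increases in knockout cells were in CSTA, a cysteine protease inhibitor of cornified epithelium, 115-fold (6.84, SE 0.46; 212-fold without knockout control replicate 3), CSF3, the granulocyte colony-stimulating factor, 90.6-fold (6.50, SE 0.24), PADI4, 88.1-fold (6.46, SE 0.34; 174-fold without knockout control replicate 1), CYP4F3, 84.5-fold (6.40, SE 0.31), and DPYSL4, 71.3-fold (6.16, SE 0.27). Their order depends on single libraries with few counts, since DSG3, at 57.9-fold, was 122-fold higher without knockout control replicate 1. ELF3 fell 31.9-fold, CA9 24.9-fold, PIF1 17.6-fold, the chemoattractant RARRES2 11.5-fold and the lipopolysaccharide co-receptor CD14 9.10-fold. The adjusted p-values of these 10 genes ran from 3.45e-10 to 5.02e-06 (edgeR). SLC25A5 rose 1.25-fold in knockout cells (0.32, SE 0.10, adjusted p = 0.0226), a call lost without knockout control replicate 3 (adjusted p = 0.0613) or knockout bleomycin replicate 2 (adjusted p = 0.0933), while SLC25A6 did not pass (0.10, SE 0.10, adjusted p = 0.475). In wild type cells neither passed, SLC25A5 at 0.20 (SE 0.10, adjusted p = 0.13) and SLC25A6 at -0.04 (SE 0.10, adjusted p = 0.782), and the interaction of SLC25A5 did not pass (0.12, SE 0.15, adjusted p = 0.91). With limma on log2(FPKM + 1), 1056 genes changed at least 2-fold in place of 2862.

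Knockout against wild type in control medium asks what differs between the genotypes without the drug, where low SLC25A4 and clone cannot be told apart. A total of 28 genes passed edgeR's test, 18 higher and 10 lower, with 9 changed at least 2-fold. Interferon-stimulated genes were among those that rose: the ubiquitin-like modifier ISG15 went from 69.1 ± 10.9 to 187 ± 55.9 CPM (2.71-fold, SD, n = 3, log2 fold change 1.44, SE 0.25, adjusted p = 0.0478), and IFI44 rose 2.38-fold (1.25, SE 0.19, adjusted p = 0.0238). ANKRD1, a mechanically regulated target of YAP, rose 2.23-fold (1.16, SE 0.15, adjusted p = 0.015), the actin-binding adaptor AFAP1L2 2.23-fold (1.15, SE 0.20, adjusted p = 0.0467) and thrombomodulin (THBD) 1.90-fold (0.93, SE 0.15, adjusted p = 0.0436). Beside SLC25A4, the retinol carrier RBP4 fell 2.83-fold (-1.50, SE 0.19, adjusted p = 0.0141), SERPINB2, which inhibits plasminogen activators, 2.57-fold (-1.36, SE 0.23, adjusted p = 0.0436), the neutrophil chemokine CXCL2 1.98-fold (-0.99, SE 0.14, adjusted p = 0.0156) and the transcription factor MSC 1.95-fold (-0.96, SE 0.15, adjusted p = 0.0416).

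All 26 interferon-stimulated genes had positive log2 fold changes, with a median of 1.06. In edgeR 2 rose over all genes tested and 24 rose adjusted over the list alone (camera adjusted p = 2.67e-27, and adjusted p = 0.188 with an estimated correlation). The p53 target list was higher, with 2 members called, CDKN1A (0.64, SE 0.09, adjusted p = 0.0238) and AEN, an apoptosis-enhancing nuclease (0.45, SE 0.08, adjusted p = 0.0467). Adjusted over the list alone 9 rose, and the median was 0.25 (adjusted p = 2.72e-07, and adjusted p = 0.147 with an estimated correlation). The NF-kB target list was lower, with a median of -0.22 (adjusted p = 1.86e-06, and adjusted p = 0.147 with an estimated correlation). Its called member was TNFAIP3 (-0.63), which restrains NF-kB signalling, and 7 fell adjusted over the list alone. CXCL8, the chemokine interleukin-8, was at -0.68 (SE 0.13, adjusted p = 0.0732), and passed without knockout control replicate 2 (-0.71, adjusted p = 0.0108). The secretory list did not pass (median -0.11, adjusted p = 0.127; 0.0122 without wild type control replicate 3).

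The mitochondrially encoded list was lower, with a median of -0.62 (adjusted p = 1.86e-06, and adjusted p = 0.566 with an estimated correlation). With edgeR 0 of its 13 members passed over all genes or adjusted over the list alone, and MT-CO1, cytochrome c oxidase subunit I, was at -0.43 (SE 0.59, adjusted p = 0.784), and at 0.10 without knockout control replicate 2. Without replicate 2 of the knockout control group the median of the mitochondrially encoded list was -0.07 (adjusted p = 0.195). The ribosomal protein list was lower as well (median -0.11, adjusted p = 0.00464, and adjusted p = 0.649 with an estimated correlation), and without that library it did not pass (adjusted p = 0.383), nor without wild type control replicate 1 (adjusted p = 0.971). The CDK inhibitor list was higher (median 0.20, adjusted p = 0.00823, and adjusted p = 0.566 with an estimated correlation), with CDKN1A called over all genes and adjusted over the list alone, and CDKN2A at 0.61 (SE 0.29), which was -0.02 without knockout control replicate 2. Without that library the CDK inhibitor list did not pass (adjusted p = 0.516), nor without wild type control replicate 1 (adjusted p = 0.0536). The glycolysis list was lower (median -0.19, adjusted p = 0.000339, and adjusted p = 0.566 with an estimated correlation), with ENO1 at -0.25 (SE 0.16, and -0.10 without knockout control replicate 2), and it did not pass without wild type control replicate 1 (adjusted p = 0.265). With edgeR 0 members of the ribosomal and glycolysis lists passed over all genes or adjusted over the list alone. The nuclear oxidative phosphorylation genes (median -0.02, adjusted p = 0.435) and the list of adenine nucleotide exchange and pore genes, to which SLC25A4 belongs (median -0.07, adjusted p = 0.127), did not pass. The list of adenine nucleotide exchange and pore genes passed, as lower, without wild type control replicate 2 (0.0229) or 3 (0.0244) or knockout control replicate 2 (0.00178).

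The number of genes called in this comparison depended on single libraries. Without knockout control replicate 2 it was 175, of which 26 were among the 28 while ISG15 (adjusted p = 0.145) and SERPINB2 (0.0719) were lost, and leaving out any other library of the comparison gave 0 to 12, with 0 without wild type control replicate 3. Without that replicate the adjusted p was 0.239 for ISG15, AFAP1L2 and AEN, 0.224 for THBD, 0.124 for IFI44, 0.117 for SERPINB2, 0.0978 for MSC and 0.096 for ANKRD1, RBP4, CXCL2 and CDKN1A. DESeq2 called 202 genes and limma-voom 10, and 1661 genes had an unadjusted p under 0.05.

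**Figure D3:**
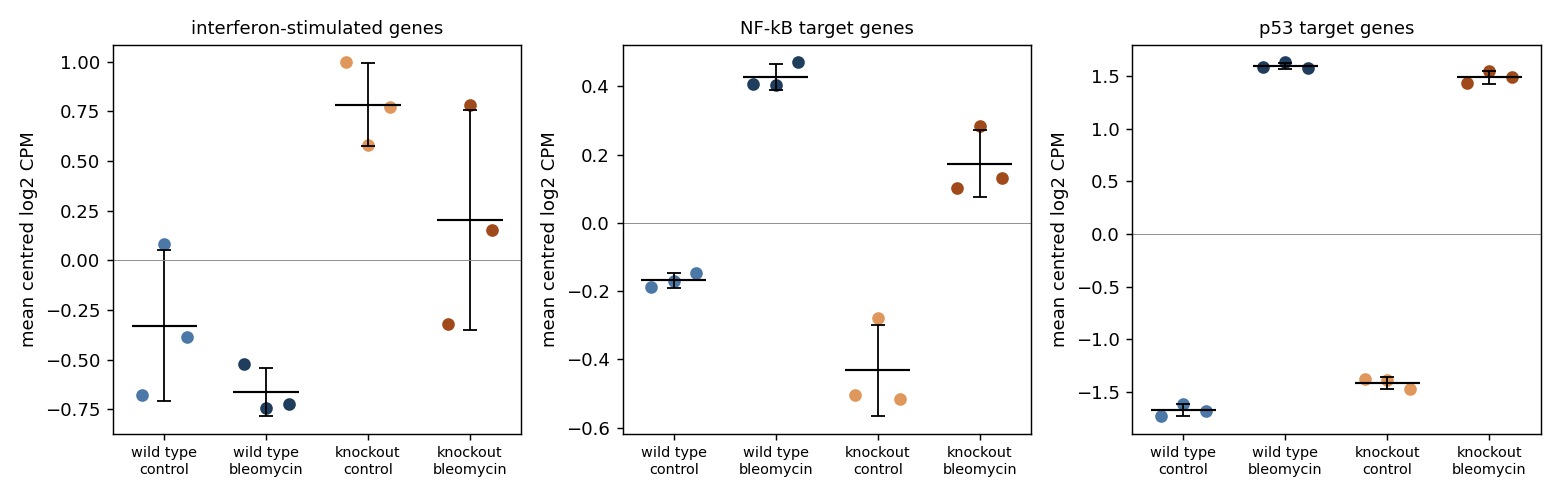
Mean centred log2 CPM of the members of 3 lists in each library: interferon-stimulated genes (26 members), NF-kB targets (15) and p53 targets (28). Points are libraries, the line is the group mean and the bar its SD (n = 3). In each medium the 3 knockout libraries lie above the 3 wild type libraries for interferon-stimulated genes and below them for NF-kB targets.

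Knockout against wild type in bleomycin asks what differs between the genotypes in cells exposed to the drug, again with low SLC25A4 and clone inseparable. With edgeR 8 genes passed, 1 higher and 7 lower, and 5 changed at least 2-fold. COL8A1, a short-chain collagen (chromosome 3, 99638475 to 99799226), was 2.03-fold higher, at 50.7 ± 4.33 against 25 ± 2.55 CPM (SD, n = 3, log2 fold change 1.02, SE 0.10, adjusted p = 0.000904). It was also higher in control medium (0.81, SE 0.09, adjusted p = 0.0111). The inflammatory cytokine IL6 was 2.19-fold lower, at 45.5 ± 13.5 against 99.7 ± 8.10 CPM (-1.13, SE 0.17, adjusted p = 0.0419), and CSF3 was 2.07-fold lower (-1.05, SE 0.15, adjusted p = 0.0414). MSC fell 2.26-fold (-1.18, SE 0.15, adjusted p = 0.021) and VAMP7, a vesicle fusion protein, 1.74-fold (-0.80, SE 0.12, adjusted p = 0.0414). GREM1, an antagonist of bone morphogenetic proteins (-0.57), and SPRTN, a protease for DNA-protein crosslinks (-0.78), were the other called genes.

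The secretory list was lower in knockout cells, with a median of -0.27 and 24 of 34 log2 fold changes negative (adjusted p = 1.74e-09, and adjusted p = 0.134 with an estimated correlation). IL6 was its called member, and adjusted over the list alone 11 fell and 1 rose. CXCL8 was at -0.56 (SE 0.13, adjusted p = 0.234). The NF-kB target list was lower, with a median of -0.20, IL6 called and 4 lower adjusted over the list alone (adjusted p = 2.47e-06, and adjusted p = 0.134 with an estimated correlation). All 26 interferon-stimulated genes were positive, with a median of 0.91 (adjusted p = 3.04e-22, and adjusted p = 0.298 with an estimated correlation). Over all genes tested 0 of them passed in edgeR, 21 rose adjusted over the list alone, and DESeq2 called 5 and limma-voom 0. OAS3, a sensor of double-stranded RNA, was at 0.56 (SE 0.16) and ISG15 at 0.66 (SE 0.24).

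The remaining lists that passed in bleomycin had medians from -0.20 for histone genes to 0.14 for cytosolic ribosomal protein genes, and 0 members called in edgeR over all genes tested. The p53 target list was lower (median -0.11, adjusted p = 0.00027, and adjusted p = 0.309 with an estimated correlation), with CDKN1A at -0.17 (SE 0.09). The mitosis list was higher (median 0.09, adjusted p = 0.000542, and adjusted p = 0.571 with an estimated correlation), with TOP2A at 0.17 (SE 0.09). The hypoxia list was higher (median 0.10, adjusted p = 0.00406, and adjusted p = 0.565 with an estimated correlation), with LOX, the collagen cross-linking enzyme, at 0.46 (SE 0.11), and 1 member, which rose, passed adjusted over the list alone. The ribosomal protein list was higher (median 0.14, adjusted p = 8.46e-05, and adjusted p = 0.751 with an estimated correlation), with RPL8 at 0.09 (SE 0.18), and lost its call without wild type bleomycin replicate 1 (0.0554) or knockout bleomycin replicate 2 (0.0637). The nuclear oxidative phosphorylation list was higher (median 0.09, adjusted p = 0.0152, and adjusted p = 0.759 with an estimated correlation), with the ATP synthase subunit ATP5F1A at 0.11 (SE 0.14), and lost its call without wild type bleomycin replicate 1 (0.438) or 2 (0.356) or knockout bleomycin replicate 2 (0.652). The histone list was lower (median -0.20, adjusted p = 0.0271, and adjusted p = 0.571 with an estimated correlation), with H1F0 at -0.18 (SE 0.08), and lost its call without wild type bleomycin replicate 3 (0.316) or knockout bleomycin replicate 1 (0.46) or 3 (0.0729). Adjusted over the list alone, 0 members of the p53, mitosis, ribosomal, oxidative phosphorylation and histone lists passed.

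In bleomycin DESeq2 called 74 genes and limma-voom 12, and 1103 genes had an unadjusted p under 0.05. Replicate 2 of the knockout control group takes no part in this contrast but enters the shared estimate of the spread, and the median dispersion was 0.0198 with it and 0.00764 without it. Without it 294 genes passed, 159 higher and 135 lower, all 8 among them, and leaving out any library of the contrast gave 2 to 4. SLC25A4 and COL8A1 passed in each of these fits, while without knockout bleomycin replicate 3 the adjusted p was 0.431 for IL6, 0.423 for CSF3 and VAMP7 and 0.163 for MSC. Between the media, 3 genes were called in both, 24 of the 28 called in control medium had the same sign in bleomycin, and all 8 called in bleomycin had the same sign in control medium. Across all genes the knockout effects in the 2 media correlated with r = 0.133, and across the called genes with r = 0.861, where genes are not independent replicates and the called ones were selected for their size. In 283 windows of 10 Mb, 0 had a called shift of knockout against wild type. A call required both media, the same sign and a median of at least 0.2. By adjusted p alone, whatever the size of the median, 9 passed in control medium and 2 in bleomycin.

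The interaction asks whether bleomycin acted differently in knockout and wild type cells. With edgeR 0 genes passed (770 with an unadjusted p under 0.05), against 4 with DESeq2 and 0 with limma-voom. CDKN1A, with a log2 difference of -0.81 (SE 0.13), and GDF15, with -1.24 (SE 0.21), shared the smallest adjusted p of 0.351, and MDM2 was at -0.62 (SE 0.13, adjusted p = 0.78). Without knockout control replicate 2, 9 genes passed, all with a lower response in knockout cells: INPP5D, AKAP9, CDKN1A, CYFIP2, THBD, CAVIN2, GALNT5, RRM2B and TLR4. All but CDKN1A were named after their values were seen. In that fit CDKN1A was at -0.84 (SE 0.12, adjusted p = 0.00774), while leaving out any other library gave 0.473 to 0.979 and the alternatives together 1.81e-07 to 0.979.

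As a list, p53 targets rose less in knockout cells. Their median interaction was -0.31, 24 of 28 were negative and 9 were lower adjusted over the list alone (camera adjusted p = 1.83e-13, and adjusted p = 0.0465 with an estimated correlation). The list stayed past the threshold without replicate 2 of the knockout control group, with a median of -0.31. In control medium the p53 targets started higher in knockout cells by a median of 0.25 and in bleomycin they ended lower by 0.11. Both differences enter the interaction, although neither passed on its own with an estimated correlation. Other lists passed with the preset correlation only. The ribosomal list had a median interaction of 0.27 (adjusted p = 4.7e-08, and adjusted p = 0.58 with an estimated correlation), glycolysis 0.22 (adjusted p = 6.84e-05, and adjusted p = 0.578 with an estimated correlation) and mitosis 0.12 (adjusted p = 0.00134, and adjusted p = 0.58 with an estimated correlation). Hypoxia response genes had a median of 0.12 (adjusted p = 0.00911, and adjusted p = 0.58 with an estimated correlation) and nuclear oxidative phosphorylation genes 0.08 (adjusted p = 0.0165, and adjusted p = 0.717 with an estimated correlation). The mitochondrially encoded list had a median of 0.71 (adjusted p = 3.32e-05, and adjusted p = 0.58 with an estimated correlation), which was 0.18 without knockout control replicate 2, where the list kept its call. Without wild type control replicate 1 the adjusted p was 0.0613 for glycolysis, 0.132 for mitosis, 0.169 for hypoxia and 0.583 for nuclear oxidative phosphorylation. The hypoxia list also lost its call without knockout control replicate 1 (adjusted p = 0.0881) or 3 (0.0816), and nuclear oxidative phosphorylation without wild type bleomycin replicate 1 (0.198) or 2 (0.129), knockout control replicate 3 (0.204) or knockout bleomycin replicate 2 (0.327). Adjusted over the list alone, 1 mitosis gene and 1 hypoxia gene were higher, and 0 members of the other 4 lists passed. Interferon-stimulated genes (median -0.16, adjusted p = 0.0529), NF-kB targets (median 0.05, adjusted p = 0.515) and secretory genes (median -0.17, adjusted p = 0.126) did not pass. The list of interferon-stimulated genes passed, as lower, without wild type control replicate 2 (9.71e-05), wild type bleomycin replicate 2 (0.0237), knockout control replicate 2 (0.000751) or knockout bleomycin replicate 2 (2.62e-08). NF-kB target genes passed, as higher, without knockout control replicate 2 (0.0154), and senescence-associated secretory genes, as lower, without knockout bleomycin replicate 2 (0.00702).

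Across genes the responses of both genotypes were close. Over the 8776 genes past the threshold in either genotype, r was 0.945, 98.4% changed in the same direction and the orthogonal slope of knockout on wild type was 0.934. Leaving out a library gave slopes of 0.897 to 0.989. In both genotypes 3143 genes rose and 2562 fell, where independent lists would share 900 and 676, and 0 genes were called in opposite directions. The comparisons share no library, and genes are not independent replicates.

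**Figure D4:**
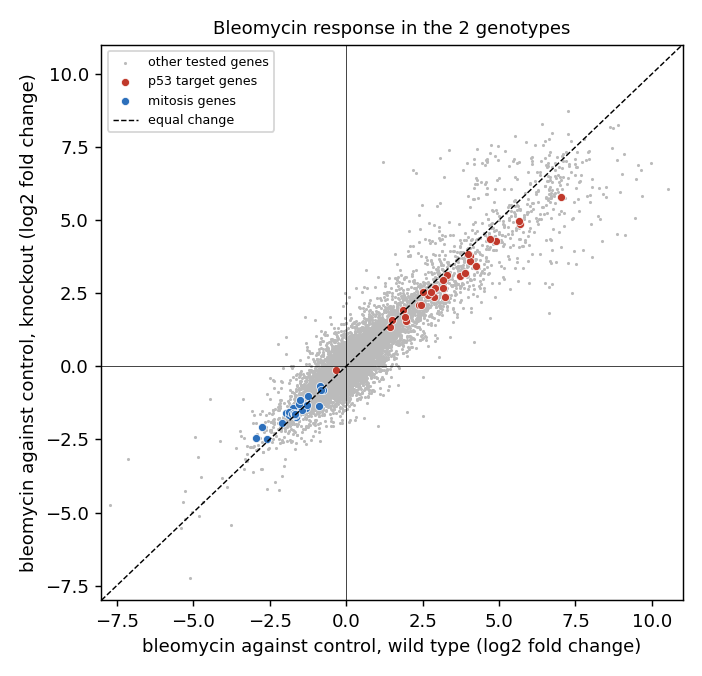
Log2 fold change of bleomycin against control in wild type cells (horizontal) and knockout cells (vertical) for each of the 16702 tested genes, with p53 targets and mitosis genes coloured. The dashed line marks an equal change. The p53 targets have a median of 3.17 in wild type and 2.67 in knockout cells.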

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

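Most tests in this part were written before their results were seen; the test for a mislabelled sample, the test of the neighbours of list members and the use of the fit without replicate 2 of the knockout control group to judge the third pattern were chosen after. Of the lists tested, 7 were flagged because their bleomycin response differed between the genotypes by the test of the interaction (camera with the preset correlation).

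The p53 target genes rose less with bleomycin in knockout cells, with a median interaction of -0.31 (adjusted p = 1.83e-13, and adjusted p = 0.0465 with an estimated correlation). Replicate 2 of the knockout control group is excluded as the cause, since the median without it was -0.31, and so is scaling between libraries, since the median nearer 0 under RLE or upper-quartile scaling was -0.29. A smaller response of all strongly rising genes remains possible: among 10000 random lists matched on the size of the response and on expression the p53 list lay at percentile 11.3, where the random lists had a median of -0.22. The smaller rise may therefore be general rather than particular to p53. An effect of low SLC25A4 on the response and a difference between cell clones cannot be told apart here, because the genotype and the clone are the same contrast.

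The mitochondrially encoded genes were flagged with a median interaction of 0.71 (adjusted p = 3.32e-05, and adjusted p = 0.58 with an estimated correlation). Without replicate 2 of the knockout control group the median was smaller, and the list still passed with the preset correlation. The pattern weighed here is that library, which moves the size of the difference. Loss of mitochondrial transcripts alone is excluded, since the SD of its nuclear deviations was 1.91 times the highest of the other libraries. GC content and transcript length explained 12.8% of the variance of its deviations against at most 4.84% elsewhere, which lies between the values set beforehand for and against that cause and leaves it open, and its mitochondrial genes lay -3.61 SD from nuclear genes matched on both, so that trend is excluded as their cause. A label swapped with another of the 4 groups is excluded, with CDKN1A at 0.0344 of the lowest bleomycin library and SLC25A4 at 0.433 of the lowest wild type library. A difference in the culture or in the handling of this RNA could each remain, and no biological explanation was tested.

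Interferon-stimulated genes were higher and NF-kB targets lower in knockout cells in both media, the third pattern weighed. As a set, the nearest genes outside the lists did not move with the members. Their change was 0.0634 times that of the interferon-stimulated genes (95% interval -0.0192 to 0.124). For the NF-kB targets, whose median in this test was only -0.12, the ratio was -0.0167 (-0.45 to 0.183). The 26 interferon-stimulated genes lie in 19 windows on 13 chromosomes and the 15 NF-kB targets in 14 windows. These medians therefore cannot exclude a gained or lost chromosome segment that holds a few members. The share in called windows, 0%, says nothing because 0 of 283 windows were called. Replicate 2 of the knockout control group is excluded, since in the fit without it both lists kept their direction in both media, with a largest adjusted p of 2.99e-06. The test chosen for spread between cultures went against it: the scores of knockout and wild type libraries overlapped in neither medium. The larger exact permutation p (two-sided, 400 labelings within media) was 0.005, the smallest possible. Both lists were weighed because they had differed in these same libraries, so the test cannot exclude spread between cultures. With estimated correlations neither list passed in control medium (adjusted p = 0.188 and 0.147) or in bleomycin (0.298 and 0.134), and an effect of low SLC25A4 or a clone difference could each give the pattern.

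The ribosomal protein genes were flagged for a median interaction of 0.27 (adjusted p = 4.7e-08). The glycolysis genes had a median interaction of 0.22 (adjusted p = 6.84e-05). The mitosis genes had a median interaction of 0.12 (adjusted p = 0.00134). The hypoxia response genes had a median interaction of 0.12 (adjusted p = 0.00911). The nuclear oxidative phosphorylation genes had a median interaction of 0.0824 (adjusted p = 0.0165). With an estimated correlation the adjusted p-values of these 5 lists were 0.58, 0.578, 0.58, 0.58 and 0.717.

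Other splits of the same libraries were tested in the same way. For contrasts between 2 groups only 10 splits exist, too few for a share under 0.05. The real split gave 7262, 7219, 28 and 8 genes for bleomycin in wild type, bleomycin in knockout, knockout in control and knockout in bleomycin. The highest other split gave 0, 0, 2 and 0, so that 1 of 10 splits, the real one, reached each count. Other splits of the bleomycin contrasts put treated and control libraries together in both groups, which raises the spread within groups. Their count of 0 was therefore largely set by the design. For the interaction the real count was 0 genes and the highest other 2, and since 60 of 60 splits reach 0 by construction this says nothing about chance. For lists, other splits called many as well: 3 of 10 splits reached the 12 lists of bleomycin in wild type (highest other 14), 1 of 10 the 15 lists in knockout (highest other 13), 5 of 10 the 7 lists of knockout in control (highest other 8) and 1 of 10 the 9 lists of knockout in bleomycin (highest other 7). For the interaction 18 of 60 splits reached the 7 lists (highest other 10), and chance cannot be excluded for their number.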

How the results depend on the processing

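Among the alternatives, the fits without replicate 2 of the knockout control group in comparisons that do not use it, the GC and length offset and the sample quality weights were chosen after seeing the data. The bleomycin comparisons kept their counts of genes within 1.5 times in every fit. RLE and upper-quartile scaling moved the share of higher calls by under 10 percentage points, and 0 windows were called under any alternative. RLE scaling ended no called list, and upper-quartile scaling was not run for the list tests. A fit without 1 library leaves 2 in that group, which limits every count below, and for other alternatives the cause was not tested.

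With log2(FPKM + 1) the bleomycin genes changed at least 2-fold numbered 1173 in wild type (1190 with no filter) and 1056 in knockout (1056 with no filter), a scale that compresses low genes. For knockout in control medium, against 28 genes, the count was 202 with DESeq2, 10 with limma-voom, 321 with no filter, 0 with only the groups compared, 13 with log2(FPKM + 1), 13 with log2(FPKM + 0.1), 10 with log2(FPKM + 1) and no filter, 45 with the GC and length offset, 972 with quality weights, and 0 to 175 leaving out a library. Of these, against 9 changed at least 2-fold, the counts were 29 with DESeq2, 5 with limma-voom, 51 with no filter, 0 with only the groups compared, 3 with log2(FPKM + 1), 5 with log2(FPKM + 0.1), 1 with log2(FPKM + 1) and no filter, 113 with quality weights, and 0 to 21 leaving out a library.

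For knockout in bleomycin, against 8 genes, the count was 74 with DESeq2, 81 with no filter, 312 with only the groups compared, 23 with log2(FPKM + 1), 5 with log2(FPKM + 0.1), 32 with log2(FPKM + 1) and no filter, 16 with the GC and length offset, 716 with quality weights, and 2 to 294 leaving out a library. Against 5 changed at least 2-fold, it was 17 with DESeq2, 25 with no filter, 23 with only the groups compared, 3 with log2(FPKM + 0.1), 2 with log2(FPKM + 1) and no filter, 72 with quality weights, and 1 to 26 leaving out a library. For the interaction, against 0 genes, it was 4 with DESeq2, 13 with no filter, 3 with log2(FPKM + 1) and no filter, 75 with quality weights, and 0 to 9 leaving out a library, of which 1, 9, 0, 15 and 0 to 1 changed at least 2-fold.

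SLC25A4 in control medium kept its direction throughout, at -1.79 with only the groups compared (adjusted p = 0.406), -1.2 with log2(FPKM + 1) and no filter (adjusted p = 0.0605), and -1.96 to -1.65 leaving out a library. In bleomycin SLC25A4 kept its call under every alternative. The lists past the threshold numbered 3 with an estimated correlation and 21 with fry for bleomycin in wild type (main 12), 5 with an estimated correlation in knockout (main 15), 0 and 3 for knockout in control medium (main 7), 0 and 0 for knockout in bleomycin (main 9), and 1 and 1 for the interaction (main 7). For knockout in control medium they numbered 13 with no filter, 4 with quality weights and 4 to 11 leaving out a library, and for the interaction 3 to 12 leaving out a library. The orthogonal slope of the bleomycin responses was 0.461 over genes past the threshold in wild type only, a set selected on the wild type change, and 0.897 to 0.989 leaving out a library. Among values past the threshold in either fit, the direction turned for TNFAIP2 in control medium with quality weights (-0.28), and for the list of cytosolic ribosomal protein genes in control medium without wild type control replicate 1 (adjusted p = 0.971, within 8.44e-06 to 0.971 leaving out a library) and with quality weights (adjusted p = 0.396). Of 4578 values of named genes compared, 60 more turned that passed in neither fit, 16 of them without knockout control replicate 2, such as CDKN2A and MT-CO1 in control medium.

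The replicate numbers do not pair the libraries: same-numbered libraries had correlations of -0.128 to 0.109, with 1 of 18 over 0.1, and 1 of 12 libraries correlated best with its own number. With the replicate number as a block, 11 genes passed for knockout in control medium and 4 for knockout in bleomycin.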

Other observations

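The tests of gene families and those of list scores per library were chosen after the data were seen. For interferon-stimulated genes and NF-kB targets the score test was written before its result was seen. Both lists were picked because they had differed in these same libraries.

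Kinesins, the motor proteins of the spindle and of transport, and nucleoporins were lower as families after bleomycin in both genotypes with the preset correlation, with members called in both directions. Families of at least 10 protein-coding genes sharing a symbol stem, 176 in all, were tested with camera. Of 32 kinesins (KIF), 14 fell and 5 rose in wild type cells (adjusted p = 0.0162, and adjusted p = 0.947 with an estimated correlation), and 17 fell and 3 rose in knockout cells (adjusted p = 0.00429, and adjusted p = 0.955 with an estimated correlation). Of 21 nucleoporins (NUP), 12 fell and 2 rose in wild type cells (adjusted p = 0.0162, and adjusted p = 0.947 with an estimated correlation), and 13 fell and 1 rose in knockout cells (adjusted p = 0.0421, and adjusted p = 0.955 with an estimated correlation). Of 12 splicing factors of the SRSF family, 8 fell and 1 rose in knockout cells (adjusted p = 0.0421, and adjusted p = 0.955 with an estimated correlation). Zinc finger genes (ZNF, 449 members) had a median of -0.09 for knockout against wild type in bleomycin (adjusted p = 0.00886, and adjusted p = 0.961 with an estimated correlation). In control medium the collagen family (COL) was higher in knockout cells, with a median of 0.42 and 1 called member (adjusted p = 0.00762), and large-subunit ribosomal protein genes (RPL) were lower (median -0.18, adjusted p = 0.0116), both with adjusted p = 0.984 with an estimated correlation. Without replicate 2 of the knockout control group neither passed (adjusted p = 0.733 for COL and 0.879 for RPL). The RPL family had a median interaction of 0.31 (adjusted p = 3.69e-06, and adjusted p = 0.987 with an estimated correlation).

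The list scores per library, the mean centred log2 CPM of the members, differed between knockout and wild type by 1.11 in control medium and 0.866 in bleomycin for interferon-stimulated genes (exact permutation over 400 labelings within media, two-sided, p = 0.005, adjusted over 5 lists 0.0125). For NF-kB targets the differences were -0.264 and -0.254 (same exact permutation test, p = 0.005, adjusted 0.0125), and for secretory genes -0.134 and -0.297 (p = 0.015, adjusted 0.025), with overlap between the genotypes in control medium. The score of p53 targets had an interaction of -0.370 (exact permutation, two-sided, p = 0.005, the smallest possible, adjusted 0.025). Genotype labels were permuted within media, so that p-value is set against no genotype difference in either medium. It is not an exact test of the interaction alone. The adjusted p-values of the list scores cover only the 5 lists scored, not all lists tested. Lists were picked for scoring after the data had been seen, and the p-values do not allow for that choice. The mitosis score did not differ by genotype (exact permutation, two-sided, p = 0.79).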
